A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

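The data are 12 dual-channel expression arrays of budding yeast, each comparing treated with untreated cells of one strain, with polyA RNA of treated cells in Cy5 and of untreated cells in Cy3 per the labels. The authors' processed table, as deposited, holds 1 column per array of log2 ratios between the channels. The unit was read from the values, since raising 2 to each value gave a whole multiple of 0.01 for 100% of the values within a tolerance of 0.001 steps. The ratios were therefore rounded to 0.01 before the log was taken, which makes low ratios coarse, and the lowest ratio of an array lay between 0.01 and 0.33. That the ratio is treated over untreated is likely from the dyes in the labels and is not written in the table. How the authors corrected background, normalized the channels and left out spots is not stated in the labels. The GenePix scanner files were not used here, so signal over background is unknown. The median of each column as deposited was 0, -0.014 and 0.014 for W303a at 1, 5 and 200 µg/ml rapamycin. It was 0, -0.014, -0.029, -0.286 and -0.014 for W303a at 0.3, 1, 3, 6 and 9 mM caffeine. It was 0.151 and 0.098 for S288c under rapamycin and caffeine, and 0.029 and 0 for Sigma 2000. Whether the authors centred the arrays is therefore unknown, and every value is reported relative to the median of its array. The unit of the rapamycin doses is the one the labels give and is doubted, since ng/ml may have been meant, which would make each dose smaller and leave the slopes on log2 dose as they are.

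Of 6219 probes, 5600 had 1 gene symbol in the platform table, 0 had several and 619 had none. All 5600 matched the RefSeq gene table of the R64 assembly by gene identifier, which changed 0 symbols. The 5600 probes named 5565 genes, and the 69 probes of 34 genes with several probes were averaged, which left 6184 genes and unnamed probes. No column was left without a sample (0 columns), and no pair of arrays shared more than 3.2% identical values. The arrays had 4915 to 5667 probes with a value, and missing values were kept as missing.

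Each array was centred on its median. Tests were run in limma 3.58.1 (R 4.3.3) with lmFit and eBayes and Benjamini-Hochberg adjustment, at a threshold of 0.05. The 6 arrays at 200 µg/ml rapamycin and 9 mM caffeine entered a fit with 1 mean per drug and 4 residual degrees of freedom, for genes with at least 2 arrays per drug. The mean of each drug was tested against 0 and against the other drug. The 8 W303a arrays entered a fit with an intercept and a slope on log2 dose per drug, for genes with all 3 rapamycin arrays and at least 4 caffeine arrays, again with 4 residual degrees of freedom. Strain differences were tested by an F test over the strain terms of an additive fit of drug and strain to the 6 arrays, with 2 residual degrees of freedom. The replicate number marks the strain, so same-numbered arrays come from the same strain. Their deviations from the drug means correlated at 0.355, 0.209 and 0.38 over 3744 genes in W303a, S288c and Sigma 2000. The block on strain was run as an alternative.

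The 35 gene lists were fixed before the data were examined, and each list with at least 5 measured members was tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Because genes had missing values, the form of camera that takes ranked statistics (cameraPR) was used in place of the planned form on the value matrix. Camera with an estimated correlation and fry were run as alternatives on genes with every value. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Medians of lists on single arrays were set against 10000 random lists of the same size.

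Named genes followed a rule fixed before the data were examined. For each drug these were the 10 highest and 10 lowest genes among those that passed with the same sign in all strains. For the drug difference they were the 5 highest and 5 lowest on the same terms, and for each slope the 5 steepest in each direction. Each list that passed added its 3 furthest members, and 25 genes were fixed by name. Alternatives fixed before the data were examined were no further centring, scaling arrays to one spread, only genes with every value, the median of a gene's probes, robust eBayes, the arrays of 1 drug alone, all 12 arrays in one fit, a block on strain, a slope on the dose itself through 0, a bound of 2-fold, and each array left out in turn. Where a drug kept 2 arrays or a slope 2 doses, the spread came from all arrays in the fit. Chosen after the data were seen were the strain block in the list tests, leave-outs for the strain test, and the list tests of strain differences with their alternatives.

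The fits were tested on 20 simulated data sets for each comparison, with 2000 changed genes of each size over the data sets (1822 to 1863 for the strain test). For rapamycin (5353 genes) 40.4% of genes changed by log2 1, 89.4% by log2 2 and 98.8% by log2 4 were called, for caffeine 38.7%, 90.8% and 98.7%, and for the drug difference 8%, 66.8% and 95.9%. For the caffeine slope (3688 genes, sizes over the whole dose range) 11.8%, 80.6% and 99.6% were called, for the rapamycin slope 7.75%, 71% and 99.5%, and for the strain test (4945 genes) 1.14%, 43.8% and 92.9%. The mean share of false calls was 4.83%, 4.93%, 4.82%, 5.09%, 4.55% and 5.59% in that order. This is the third version of the simulation, and both changes were made after false calls above the threshold had been seen. The first version drew gene variances from limma's moderated estimates, used 1 data set, and gave too many false calls for the drug difference and the strains. The second drew variances from the prior that limma fitted and added the largest size, and with 1 data set its share of false calls was still above the threshold in every comparison, most of all for the strains. The third averaged 20 data sets, so the means above hide the spread between data sets, and a single data set can hold a higher share. Simulated genes were independent, unlike real genes. In a simulated drug difference of 5353 genes, 1 of 1 list shifted by -0.5 was called and 0 of 34 other lists.

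Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the table, and matplotlib 3.10.9 drew the figures. No array was left out. A difference between strains under 1 drug has no test here, since each strain had 1 array per drug.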

Results

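Budding yeast of 3 laboratory strains, W303a, S288c and Sigma 2000, was grown in the rich medium YPD and treated with rapamycin, an inhibitor of the TOR kinase, or with caffeine, a purine analogue. Treated and untreated cells of one strain were compared on each of 12 dual-channel arrays, which measured polyA RNA. W303a received rapamycin at 1, 5 and 200 µg/ml and caffeine at 0.3, 1, 3, 6 and 9 mM. The rapamycin unit is the one in the labels and is doubted, since ng/ml may have been meant, which the values cannot settle. S288c and Sigma 2000 received 200 µg/ml rapamycin and 9 mM caffeine. The 12 arrays thus formed 8 groups, and both highest doses had n = 3, with 1 array per strain, while every other dose had 1 array and no replicate. Between 4915 and 5667 of the 6219 probes had a value on an array. Values are log2 ratios of treated over untreated cells, a direction called likely from the dyes in the labels. The strains stand in for replicates at the highest doses, so the p-values measure the spread between strains, and the number of arrays limits the precision. That spread is pooled over both drugs, so the error and p-value of a gene under 1 drug can stem from the arrays of the other drug. Errors are standard errors (SE) of the fit unless named otherwise.

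The number of genes that differed at least 2-fold from untreated cells grew with the dose in W303a. At 0.3 mM caffeine 4 genes were higher and 3 lower, at 1 mM 24 and 5, at 3 mM 292 and 185, at 6 mM 641 and 704, and at 9 mM 768 and 771. Rapamycin gave 52 higher and 53 lower at 1 µg/ml, 104 and 124 at 5 µg/ml, and 521 and 710 at 200 µg/ml. In S288c, 703 genes were higher and 816 lower under rapamycin, and 778 and 791 under caffeine. In Sigma 2000, 688 and 831 were counted under rapamycin and 762 and 862 under caffeine. The array at 1 µg/ml rapamycin resembled no other array, with correlations across genes between -0.015 and 0.191, and genes are not independent replicates in such a correlation. Its 52 higher and 53 lower genes may therefore not be a response to the drug.

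**Figure D1:**
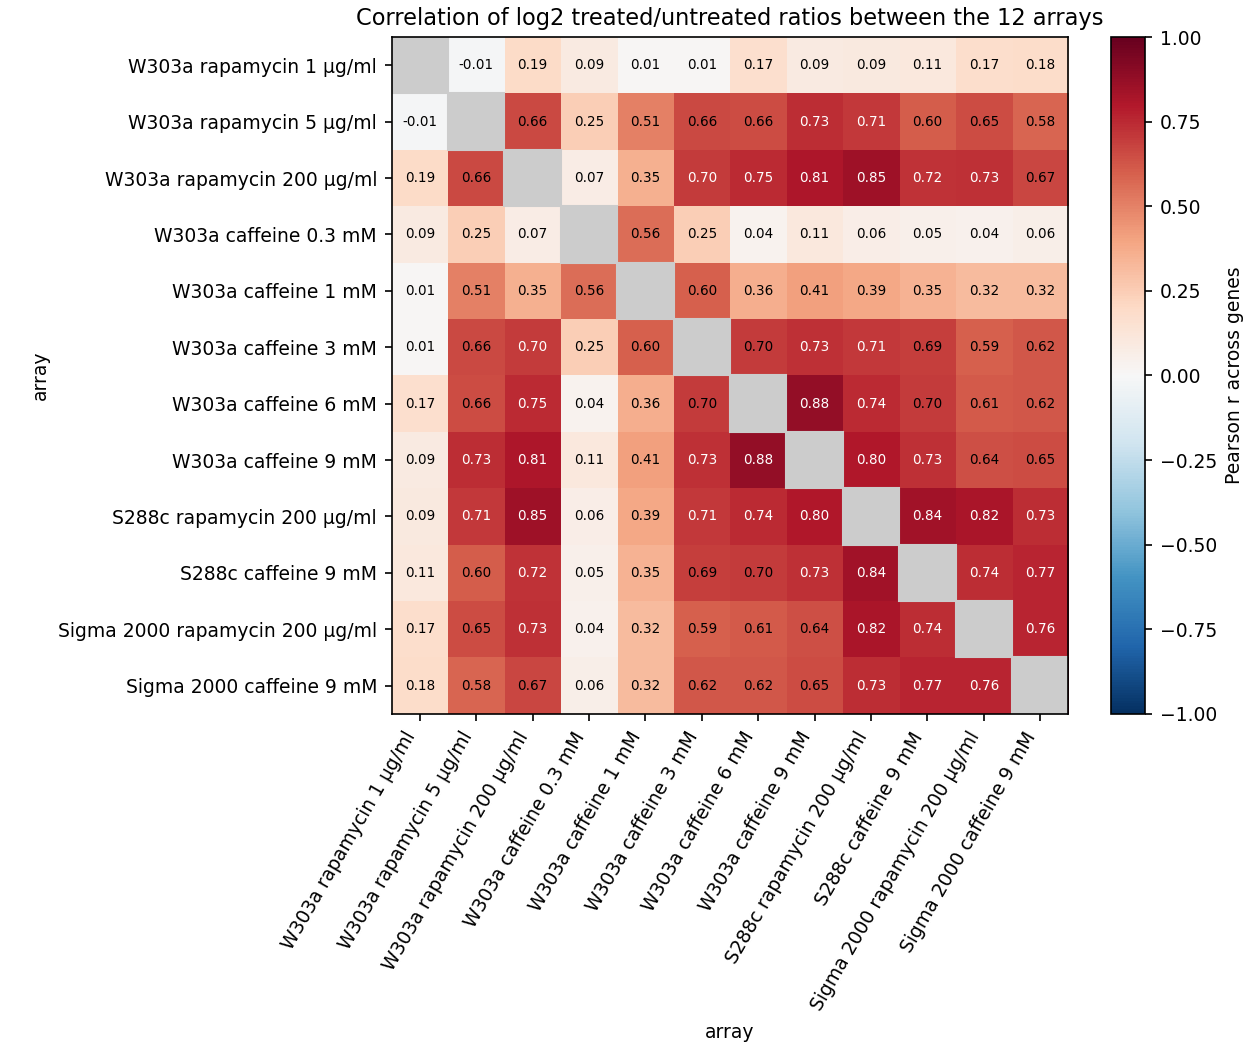
Pearson correlation of the log2 treated/untreated ratios across genes for every pair of the 12 arrays, with the arrays on both axes. The 6 arrays at the highest doses correlate at 0.642 to 0.849, while the array at 1 µg/ml rapamycin stays at or below 0.191 with every other array.

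The first comparison asked which transcripts responded to 200 µg/ml rapamycin in the 3 strains. Permease genes for nitrogen sources were among the highest. MEP2 (YNL142W), the high-affinity ammonium permease, rose 65.8-fold (log2 6.04 ± 0.43, n = 3, adjusted p = 0.000159), DAL5 (YJR152W), the allantoate permease, rose 55.7-fold (log2 5.80 ± 0.77), and GAP1 (YKR039W), the general amino acid permease, rose 52.6-fold (log2 5.72 ± 0.81). The log2 ratio of GAP1 was 2.81 in W303a, 7.70 in S288c and 6.64 in Sigma 2000, and its mean was 7.17 without W303a and 4.72 without S288c. With 1 array per strain, a difference between strains under rapamycin has no test. MEP2 had a mean of 6.78 without W303a. DAL5 stood at 5.80, 5.76 and 5.84 in W303a, S288c and Sigma 2000, so its SE stems mainly from the caffeine arrays (7.15, 2.16 and 4.38). Among the lowest were the ribosome assembly factor gene RPF2 (YKR081C) at log2 -4.41 ± 0.21, the nucleolin-like NSR1 (YGR159C) at -4.27 ± 0.29, and the RNA helicase gene DRS1 (YLL008W) at -4.29 ± 0.52. The lowest value of all genes that passed in the same direction in every strain belonged to RKI1 (YOR095C), the ribose-5-phosphate isomerase of the pentose phosphate pathway, at -5.32 ± 0.69. In Sigma 2000 it stood at -6.67, the lowest ratio of that array (0.01) and the smallest step of the rounded ratios, against -4.07 in W303a and -5.21 in S288c.

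In limma's test, 1804 of 5353 genes and unnamed probes passed an adjusted p of 0.05 under rapamycin, 834 higher and 970 lower, and 122 of them were unnamed probes. Without further centring 942 were higher and 889 lower, so which direction held more genes depends on the centring. Among the highest were also DAL7, a malate synthase of allantoin breakdown (log2 5.10 ± 0.36), TMT1, a methyltransferase (4.95 ± 0.20), the vacuolar carboxypeptidase gene CPS1 (4.55 ± 0.26), the vacuolar aminopeptidase gene APE1 (4.19 ± 0.31), the arginine synthesis gene ARG4 (4.18 ± 0.55) and the carnitine acetyltransferase gene YAT2 (3.91 ± 0.51). SRY1 stood at 4.52 ± 0.98, with 4.47, 4.83 and 4.25 in W303a, S288c and Sigma 2000. Its SE stems mainly from the caffeine arrays (4.55, 2.92 and -1.60). RMT2 (-4.41 ± 0.18), LIA1 (-3.91 ± 0.20) and the ribosome assembly genes NOP7 (-4.01 ± 0.49), ENP1 (-4.00 ± 0.20), HCA4 (-3.85 ± 0.24) and BRX1 (-3.80 ± 0.29) fell too. Without the S288c rapamycin array 821 genes passed, and SRY1 kept a log2 ratio of 4.36 but not its call (adjusted p = 0.0619), while without the Sigma 2000 rapamycin array 1106 passed. Other means moved by over 1.5-fold without 1 array and kept their call. Without W303a these were RKI1 (-5.94), DRS1 (-5.15), NOP7 (-4.73), RPL13B (-4.15) and CRG1 (3.68), without S288c YAT2 (3.02), and without Sigma 2000 RKI1 (-4.64) and RPL13B (-2.74). Requiring a change of at least 2-fold as well left 1167 genes.

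Of the 35 gene lists fixed beforehand, 16 shifted under rapamycin in the camera test with a preset correlation of 0.01, and 0 of them passed with an estimated correlation. Of 128 ribosomal protein genes 124 fell, or 125 adjusted over the list alone, with a median log2 ratio of -2.38, and RPS22A (-3.77 ± 0.25), RPL13B (-3.52 ± 0.46), RPS6A (-2.52 ± 0.20) and RPL3 (-2.17 ± 0.28) were among them. Of 146 ribosome biogenesis genes 136 fell, or 138 adjusted over the list alone, with a median of -2.61, DBP2 at -5.07 ± 0.48 (n = 2) and NOP1 at -3.17 ± 0.20. For these lists the adjusted p was 0.234 and 0.114 with an estimated correlation. Translation factors (32 of 38 fell, also 32 adjusted over the list alone, median -1.33), tRNA synthetases (12 of 21 fell, or 13 adjusted over the list alone, median -0.71) and RNA polymerases I and III (22 of 35 fell and 2 rose, or 23 and 4 adjusted over the list alone, median -1.07) were lower. Among them were GCD10 at -3.07 ± 0.42, YHR020W at -2.29 ± 0.21 and RPA43 at -3.57 ± 0.27. Their adjusted p was 0.0741, 0.118 and 0.28 with an estimated correlation.

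Among the raised lists, 31 of 44 genes of nitrogen catabolite repression rose, or 34 adjusted over the list alone where 1 fell, with a median of 2.51, and these included the repressor gene DAL80 (4.31 ± 0.68, n = 2) and GLN1, glutamine synthetase (2.68 ± 0.23). Their adjusted p was 0.118 with an estimated correlation. Targets of retrograde signalling from mitochondria (8 of 14 rose, also 8 adjusted over the list alone, median 1.30) included CIT2, the peroxisomal citrate synthase (4.04 ± 0.28, n = 2), and DLD3, a lactate dehydrogenase (2.67 ± 0.18). Genes of the tricarboxylic acid cycle and respiratory chain (17 of 47 rose and 1 fell, or 23 and 1 adjusted over the list alone, median 0.60) included CIT1 (2.62 ± 0.27) and ACO1 (2.41 ± 0.27). These lists had an adjusted p of 0.28 and 0.305 with an estimated correlation. Autophagy genes (15 of 27 rose, or 18 adjusted over the list alone, median 0.90), with ATG8 at 1.94 ± 0.20, and vacuolar hydrolases (7 of 15 rose and 1 fell, the same counts adjusted over the list alone, median 0.97) had an adjusted p of 0.151 and 0.171 with an estimated correlation. Stress-induced genes (36 of 72 rose and 1 fell, or 42 and 3 adjusted over the list alone, median 1.00), with the catalase gene CTT1 at 1.91 ± 0.44 (n = 2), had an adjusted p of 0.28 with an estimated correlation.

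Shifts were also seen in 5 further lists. Cell wall integrity genes (21 of 54 rose and 2 fell, or 22 and 2 adjusted over the list alone, median 0.36) included CRG1 (3.01 ± 0.41) and the MAP kinase gene SLT2 (2.0 ± 0.24). Amino acid biosynthesis genes (22 of 59 rose and 7 fell, the same counts adjusted over the list alone, median 0.37) included HIS4 (2.87 ± 0.29). Their adjusted p was 0.606 and 0.658 with an estimated correlation. Oxidative stress genes controlled by Yap1 (5 of 22 rose, or 4 adjusted over the list alone, median 0.65) included the drug exporter gene ATR1 (4.37 ± 0.51, n = 2), with an adjusted p of 0.234 with an estimated correlation. For proteasome genes (4 of 36 rose, or 0 adjusted over the list alone, median 0.34) and mitochondrial ribosomal protein genes (4 of 64 rose, or 0 adjusted over the list alone, median 0.26) the adjusted p was 0.916 and 0.918 with an estimated correlation. Without the Sigma 2000 rapamycin array the median of the proteasome list was 0.20 (adjusted p = 0.125) and that of the mitochondrial ribosome list turned to -0.03 (adjusted p = 1), so the shifts of these lists rest on that array. Of the fixed single genes, ADE17 of purine synthesis rose (3.07 ± 0.55), the phosphate transporter gene PHO84 (-2.05 ± 0.38) and the G1 cyclin gene CLN3 (-1.59 ± 0.27) fell, and HSP12 (0.20 ± 0.75), the drug pump gene PDR5 (-0.87 ± 0.28) and TOR1 (-0.39 ± 0.17) did not pass.

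**Figure D2:**
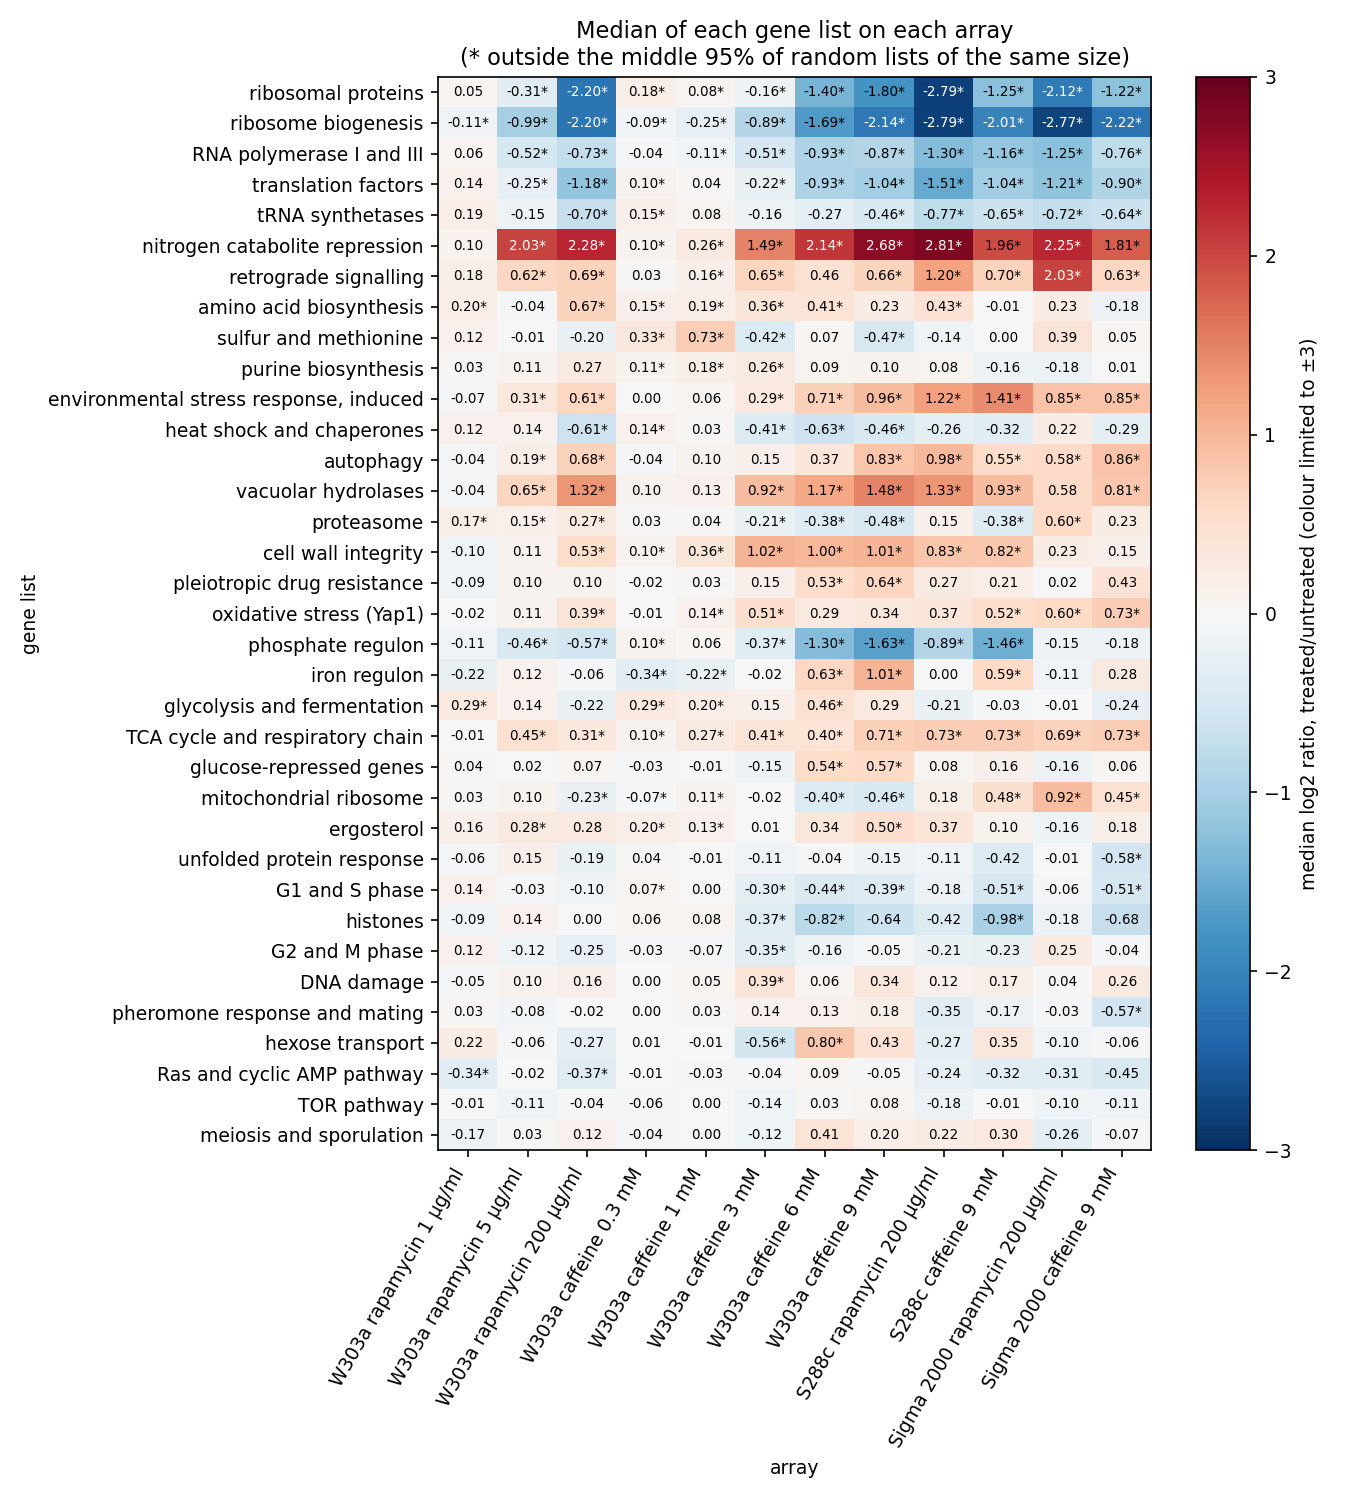
Median log2 treated/untreated ratio of each of the 35 gene lists (vertical axis) on each of the 12 arrays (horizontal axis), as colour and as a number. A star stands for a median outside the middle 95% of 10000 random lists of the same size, and the medians of ribosome biogenesis genes in W303a went from -0.89 at 3 mM to -2.17 at 9 mM caffeine over the genes measured at both doses.

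The second comparison asked the same of 9 mM caffeine. The highest gene was ARO10 (YDR380W), phenylpyruvate decarboxylase of aromatic amino acid breakdown, which rose 36.7-fold (log2 5.20 ± 0.62, n = 3, adjusted p = 0.00152), and ARO9 (YHR137W), the aromatic aminotransferase of the same pathway, rose 34.5-fold (5.11 ± 0.48), or log2 4.39 without the Sigma 2000 caffeine array. MEP2 rose 35.7-fold (5.16 ± 0.43), and DAL5 (4.56 ± 0.77), DAL7 (4.29 ± 0.36) and DAL4, the allantoin permease (4.06 ± 0.86), rose as well. CIT2 rose 23.0-fold (4.52 ± 0.23), and so did MSC1 (4.57 ± 0.53), TMT1 (4.30 ± 0.20) and GCV2, a subunit of glycine decarboxylase (4.07 ± 0.50). The lowest were the RNA helicase gene DBP2 (-4.81 ± 0.39), RKI1 (-4.66 ± 0.69), the ribosome assembly genes YTM1 (-4.32 ± 0.63), NSR1 (-3.80 ± 0.29), RPF2 (-3.61 ± 0.21) and NOP7 (-3.48 ± 0.49), the adenine deaminase gene AAH1 (-3.73 ± 0.32), RMT2 (-3.53 ± 0.18), PHO84 (-3.51 ± 0.38) and LIA1 (-3.48 ± 0.20). RKI1 and YTM1 both stood at -6.64 in Sigma 2000, the lowest ratio of that array (0.01), while YTM1 stood at -3.17 in W303a and -3.16 in S288c.

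By limma's test, 1958 of 5353 genes and unnamed probes passed under caffeine, 951 higher and 1007 lower, with 135 unnamed probes among them, and without further centring 979 were higher and 952 lower. Without the S288c caffeine array 1131 passed, and 1243 were also changed at least 2-fold. Some means moved by over 1.5-fold without 1 caffeine array and kept their call. Without W303a these were DAL5 (3.27), DAL4 (2.89) and RKI1 (-5.40), and without S288c DAL5 (5.76), DAL4 (5.23), GCV2 (4.66), YTM1 (-4.91) and ADE17 (4.69). Without Sigma 2000 they were GCV2 (3.33), RKI1 (-3.66), YTM1 (-3.16) and ADE17 (3.09).

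Under caffeine 17 lists shifted with the preset correlation and 0 with an estimated one. Ribosomal protein genes (119 of 128 fell, or 124 adjusted over the list alone, median -1.43) and ribosome biogenesis genes (137 of 146 fell, or 140 adjusted over the list alone, median -2.17) were lower, with RPS22A at -2.54 ± 0.25 and NOP1 at -2.19 ± 0.20. The adjusted p of these lists was 0.297 and 0.14 with an estimated correlation. Translation factors (28 of 38 fell, or 31 adjusted over the list alone, median -1.02), tRNA synthetases (10 of 21 fell, or 11 adjusted over the list alone, median -0.57) and RNA polymerases I and III (19 of 35 fell and 1 rose, or 21 and 2 adjusted over the list alone, median -0.88) were lower too. Among them were SUI1 at -2.31 ± 0.16, CRS1 at -1.41 ± 0.19 and RPA43 at -3.01 ± 0.27. They had an adjusted p of 0.12, 0.147 and 0.297 with an estimated correlation. Genes of the G1 and S phases (13 of 33 fell and 3 rose, or 15 and 3 adjusted over the list alone, median -0.50), with POL30, the replication clamp, at -2.44 ± 0.26, and histones (4 of 10 fell, or 5 adjusted over the list alone, median -0.83), with HHF1 at -1.13 ± 0.16, both had an adjusted p of 0.297 with an estimated correlation. The phosphate regulon (8 of 20 fell and 2 rose, the same counts adjusted over the list alone, median -1.03), with SPL2 at -2.57 ± 0.32, had an adjusted p of 0.542 with an estimated correlation.

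Nitrogen catabolite repression genes rose in 30 of 44 cases and fell in 1, or 33 and 1 adjusted over the list alone, with a median of 2.29, GLN1 at 2.06 ± 0.23, and an adjusted p of 0.147 with an estimated correlation. Stress-induced genes (43 of 72 rose and 1 fell, or 49 and 1 adjusted over the list alone, median 1.22), with TFS1 at 3.90 ± 0.53 and CTT1 at 1.97 ± 0.36, had an adjusted p of 0.271 with an estimated correlation. Cell wall integrity genes (23 of 54 rose and 1 fell, or 25 and 3 adjusted over the list alone, median 0.73) included CRG1 (3.81 ± 0.41), SLT2 (1.81 ± 0.24) and the glucan synthase gene GSC2 (1.14 ± 0.26). Iron regulon genes (7 of 22 rose, also 7 adjusted over the list alone, median 0.52) included the cell wall mannoprotein gene FIT2 (2.12 ± 0.32) and the siderophore transporter gene ENB1 (1.53 ± 0.20). Retrograde signalling genes (5 of 14 rose and 1 fell, the same counts adjusted over the list alone, median 0.48) included DLD3 (2.92 ± 0.18). For each of these 3 lists the adjusted p was 0.443 with an estimated correlation. Genes of the tricarboxylic acid cycle and respiratory chain (21 of 47 rose and 2 fell, or 24 and 2 adjusted over the list alone, median 0.64) included CIT1 (2.93 ± 0.27). Yap1 targets (10 of 22 rose and 2 fell, or 12 and 2 adjusted over the list alone, median 0.65) included ATR1 (3.18 ± 0.42). Both had an adjusted p of 0.297 with an estimated correlation. Autophagy genes (14 of 27 rose, or 16 adjusted over the list alone, median 0.71), with ATG8 at 1.63 ± 0.20, and vacuolar hydrolases (7 of 15 rose, also 7 adjusted over the list alone, median 0.96), with CPS1 at 3.78 ± 0.26, had an adjusted p of 0.168 and 0.183 with an estimated correlation.

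Some caffeine calls ended without 1 array. Without the S288c caffeine array the iron list kept its median of 0.52 (adjusted p = 0.0632), histones stood at -0.58 (0.065) and GAP1 at 3.26 (0.0614), against 3.56 ± 0.81 with all arrays. GAP1 was 3.06, 4.18 and 3.46 under caffeine in W303a, S288c and Sigma 2000, so its SE stems mainly from the rapamycin arrays. The retrograde list stood at 0.33 without the S288c rapamycin array (adjusted p = 0.0532) and at 0.14 without the Sigma 2000 caffeine array (0.0505). The phosphate list stood at -1.03 without the W303a rapamycin (0.0566), -0.80 without the S288c rapamycin (0.0548) and -1.01 without the W303a caffeine array (0.0624). With only genes that had every value, 4 lists did not pass, namely retrograde signalling (median 0.25, adjusted p = 0.1), Yap1 targets (0.66, 0.0661), the phosphate regulon (-1.26, 0.0783) and G1 and S phase (-0.47, 0.0661). ADE17 rose (3.97 ± 0.55), while HSP12 (1.11 ± 0.75), PDR5 (-0.53 ± 0.28), TOR1 (0.08 ± 0.17), CLN3 (-0.70 ± 0.27) and ARG1 (1.48 ± 0.75) did not pass. ARG1 passed without the Sigma 2000 caffeine array (2.49, adjusted p = 0.0323), as did PDR5 without the W303a caffeine array under rapamycin (-0.87, adjusted p = 0.0191) and under caffeine (-0.91, adjusted p = 0.0345). PDR5 also passed under rapamycin with arrays scaled to one spread (-0.94, adjusted p = 0.0374), with only genes that had every value (0.0429) and with only the rapamycin arrays (0.0351), so its call depends on the setting.

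The calls of both drugs were then set side by side. Higher under both were 617 genes, against 148 for independent lists of these sizes, and lower under both were 760, against 182. Both calls use the same estimate of the spread of a gene, so the lists are not independent, and the excess can overstate a common response. Whether the rapamycin and caffeine arrays of a strain shared untreated cells is not stated in the labels, so part of the overlap may be shared chance values. The only gene called in opposite directions was MET17 (YLR303W), O-acetylhomoserine sulfhydrylase of methionine synthesis, which was chosen after its values were seen. MET17 stood at 1.19 ± 0.31 under rapamycin (n = 2) and -0.97 ± 0.25 under caffeine (n = 3). Its caffeine call ended without the W303a (-0.71, adjusted p = 0.0806) or the Sigma 2000 caffeine array (-0.92, 0.0867) and with only the caffeine arrays (-0.97, 0.0546). Pairs of arrays from different strains share no untreated RNA, and there the mean correlation of rapamycin with caffeine was 0.717 (SD 0.0556, 6 pairs), against 0.802 (SD 0.0403, 3 pairs) within a strain. Between strains it was 0.799 for rapamycin and 0.718 for caffeine.

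**Figure D3:**
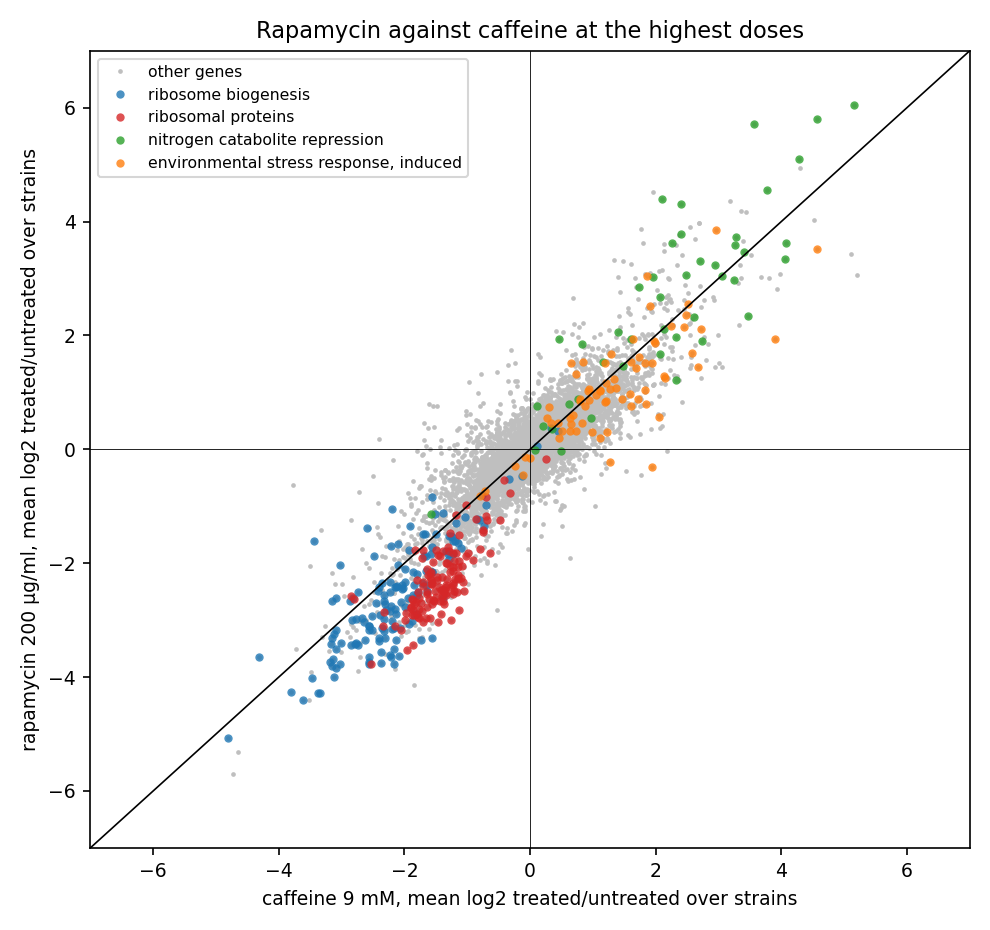
Mean log2 treated/untreated ratio over strains of each gene under 9 mM caffeine (horizontal axis) and 200 µg/ml rapamycin (vertical axis), with 4 gene lists in colour and the line of equal change. Ribosomal protein genes lie below the line, with medians of -2.38 under rapamycin and -1.43 under caffeine.

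The third comparison asked where the drugs differed at their highest doses. No single gene passed limma's test of the difference, in which 0 of 5353 genes had an adjusted p under 0.05 and 403 had an unadjusted one under 0.05, against 267.7 expected by chance, and the smallest adjusted p was 0.467. Blocking on strain also gave 0. In 11 lists the members as a group differed from other genes with the preset correlation, and in 0 with an estimated one. Ribosomal protein genes were lower under rapamycin than under caffeine by a median log2 difference of -0.90, with RPL38 at -1.75 ± 0.42, RPL6B at -1.68 ± 0.35 and RPS6A at -0.87 ± 0.29. None of the 128 passed over all genes and 37 were lower adjusted over the list alone, and the adjusted p of the list was 2.1e-35 with the preset and 0.348 with an estimated correlation. Ribosome biogenesis genes (median difference -0.45, DIP2 at -1.60 ± 0.31), translation factors (-0.36, NIP1 at -1.28 ± 0.41) and the iron regulon (-0.62, ENB1 at -1.91 ± 0.28 and FRE1, a ferric reductase, at -1.55 ± 0.34) were lower under rapamycin as well, also with an adjusted p of 0.348 with an estimated correlation. Adjusted over the list alone, 4 iron genes were lower and 0 genes of the other lists passed. The hexose transporter list was lower (-0.38, HXT4 at -1.16 ± 0.28) with an adjusted p of 0.521 with an estimated correlation.

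Higher under rapamycin than under caffeine were the lists of amino acid biosynthesis (median difference 0.39, ARG1 at 1.82 ± 1.06), the proteasome (0.56, RPN10 at 1.11 ± 0.30 and PRE10 at 1.15 ± 0.37) and nitrogen catabolite repression (0.33, GAP1 at 2.15 ± 1.15). So were those of G1 and S phase (0.35, MSH6 at 1.32 ± 0.52), histones (0.47, HTB2 at 0.90 ± 0.28) and the unfolded protein response (0.13, KAR2, the chaperone of the endoplasmic reticulum, at 0.99 ± 0.45). The adjusted p was 0.348 for amino acid biosynthesis and histones, 0.41 for the proteasome, nitrogen catabolite repression and unfolded protein response, and 0.322 for G1 and S phase with an estimated correlation. ARG1 stood at 4.27, 4.25 and 1.38 under rapamycin and at 2.54, 2.44 and -0.56 under caffeine in W303a, S288c and Sigma 2000. Its SE thus stems mainly from the spread between strains, which the fit without a strain block leaves in the error. Its difference between the drugs was similar in every strain. Over all genes and adjusted over the list alone, 0 members of these lists passed. The strains did not share the sign of 2 of these differences. The nitrogen list stood at -0.29 in W303a, 1.04 in S288c and 0.24 in Sigma 2000, and the unfolded protein list at -0.19, 0.17 and 0.46. The nitrogen list did not pass without the S288c rapamycin (median 0.03, adjusted p = 0.18) or S288c caffeine array (0.27, 0.072). The unfolded protein list did not pass without the Sigma 2000 rapamycin (0.22, 0.102) or Sigma 2000 caffeine array (0.08, 0.244). The hexose list stood at -0.95 in W303a, -0.17 in S288c and -0.02 in Sigma 2000, so W303a carried most of it. It did not pass without the W303a rapamycin (-0.31, 0.194), W303a caffeine (-0.26, 0.683) or S288c caffeine array (-0.41, 0.0686), nor with only genes that had every value (-0.27, 0.207).

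The fourth comparison asked which transcripts followed the caffeine dose in W303a, as the slope of the log2 ratio per doubling of the dose over 5 doses with 1 array each. The allantoin permease gene DAL4 rose most steeply (1.84 ± 0.35 per doubling, adjusted p = 0.00737), followed by DAL5 (1.54 ± 0.26) and the asparaginase genes ASP3-2 (1.15 ± 0.14) and ASP3-3 (1.07 ± 0.14), near-identical copies whose probes may not tell them apart. The peptide transporter gene OPT2 (1.02 ± 0.17), CPS1 (0.98 ± 0.11), MEP2 (0.94 ± 0.23), ADE17 (0.77 ± 0.10) and GAP1 (0.50 ± 0.16) rose too. DBP2 (-0.97 ± 0.10), LIA1 (-0.84 ± 0.11), RMT2 (-0.83 ± 0.10), the methionine permease gene MUP1 (-0.82 ± 0.20) and the ribosome assembly gene EBP2 (-0.79 ± 0.12) fell most steeply.

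In limma's test of the caffeine slope, 835 of 3688 genes and unnamed probes passed, 310 rising and 525 falling. With the preset correlation 19 lists passed, and 0 with an estimated one, where the adjusted p was 0.34 for each list named next. Ribosomal protein genes (107 of 120 fell, or 116 adjusted over the list alone, median slope -0.40), ribosome biogenesis (95 of 112 fell and 1 rose, or 102 and 1, median -0.44), RNA polymerases I and III (7 of 18 fell, or 10, median -0.23) and translation factors (24 of 39 fell, or 28, median -0.28) fell, each second count being adjusted over the list alone. Nitrogen catabolite repression (21 of 33 rose and 1 fell, or 25 and 1, median 0.50), stress-induced genes (16 of 53 rose and 2 fell, or 23 and 2, median 0.16) and vacuolar hydrolases (8 of 13 rose, or 10, median 0.30) rose. So did cell wall integrity (11 of 41 rose and 1 fell, or 12 and 1, median 0.18), drug resistance (4 of 17 rose, or 5, median 0.14) and the iron regulon (6 of 16 rose, or 9, median 0.26). The phosphate regulon fell (9 of 15, or 10 with 2 rising adjusted over the list alone, median -0.40), with PHO84 at -0.70 ± 0.17 and the acid phosphatase gene PHO11 at -0.66 ± 0.09, and had an adjusted p of 0.41 with an estimated correlation. Of the 34 lists tested, 8 more passed with all 5 arrays (tRNA synthetases, sulfur and methionine, heat shock, autophagy, respiration, G1 and S phase, histones and the mitochondrial ribosome), with an adjusted p between 0.34 and 0.697 with an estimated correlation. The first 7 lost the call without the 0.3 mM array (adjusted p between 0.0576 and 0.166), while most median slopes kept their size. They were -0.13 against -0.12 for tRNA synthetases, -0.34 against -0.21 for sulfur and methionine, -0.17 against -0.22 for heat shock and 0.11 against 0.15 for autophagy. They were 0.05 against 0.11 for respiration, -0.18 against -0.14 for G1 and S phase and -0.24 against -0.18 for histones. Sulfur and methionine lost it with any of the 5 arrays left out, with median slopes of -0.14, -0.21, -0.19 and -0.19 without the 1, 3, 6 and 9 mM array, against -0.21. Autophagy also lost it without the 1, 6 or 9 mM array (0.10, 0.17 and 0.05 against 0.15, adjusted p = 0.112, 0.0619 and 0.191), and histones without the 1, 3 or 6 mM array (-0.18, -0.19 and -0.15 against -0.18, adjusted p = 0.102, 0.0728 and 0.0667). So did tRNA synthetases without the 1 or 9 mM array (-0.12 in both, adjusted p = 0.0514 and 0.0726). The mitochondrial ribosome lost it without the 1, 6 or 9 mM array (0.102, 0.102 and 0.0965), with median slopes of -0.11, -0.09 and -0.11 against -0.10. With only genes that had every value, sulfur and methionine (-0.19, 0.232), autophagy (0.11, 0.106) and histones (-0.18, 0.0561) did not pass.

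Without the 0.3, 1, 6 or 9 mM array 516, 457, 396 or 150 genes passed the caffeine slope test. Without the 9 mM array MUP1 (slope -0.53, adjusted p = 0.136), PHO84 (-0.37, 0.115), MEP2 (0.91, 0.0958) and GAP1 (0.45, 0.209) did not pass. MEP2 (0.91, 0.0624) and GAP1 (0.48, 0.139) did not pass without the 6 mM array, nor GAP1 without the 1 mM array (0.43, 0.0858) or without further centring (0.47, 0.0634), with slopes near those with all arrays. Scaling every array to one spread removes growth of the whole response with dose, but also enlarges the noise of the low dose arrays. A call lost by it therefore cannot show that a slope was only such growth. After this scaling 173 genes passed, 26 rising and 147 falling. Most of the genes named above then lost their call, namely DAL4 (0.95, adjusted p = 0.161), DAL5 (0.84, 0.238), ASP3-3 (0.56, 0.0763), OPT2 (0.36, 0.418), CPS1 (0.49, 0.122), MEP2 (0.10, 0.903) and ADE17 (0.31, 0.282) among the rising ones. DBP2 (-0.47, adjusted p = 0.0782), MUP1 (-0.72, 0.0687), EBP2 (-0.39, 0.139) and PHO84 (-0.39, 0.129) lost it among the falling ones, and the slope of GAP1 turned to -0.16 (adjusted p = 0.756). ASP3-2 (0.65, adjusted p = 0.0473), LIA1 (-0.42, 0.019), RMT2 (-0.42, 0.0215) and PHO11 (-0.50, 0.019) kept theirs. A slope on the dose itself through 0 called 1897.

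**Figure D4:**
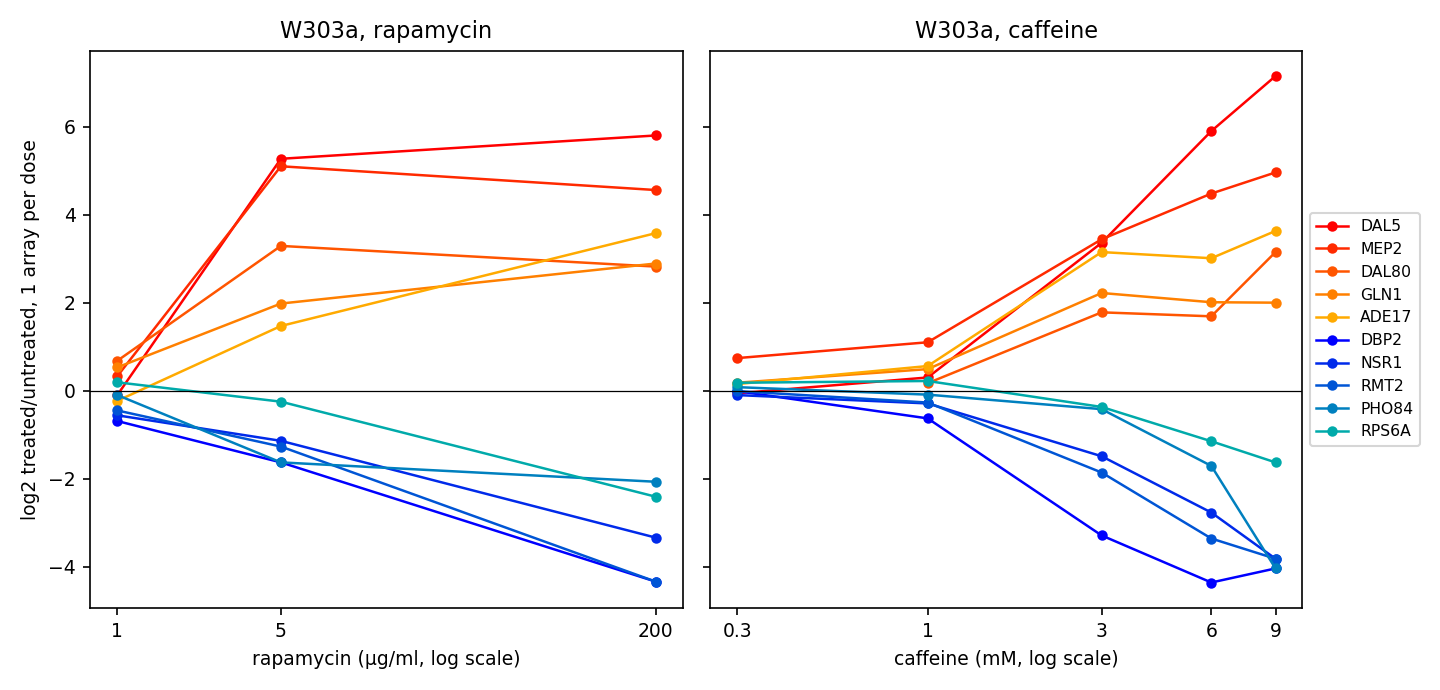
Log2 treated/untreated ratio of 10 genes in W303a (vertical axis) against the dose of rapamycin in µg/ml (left) and caffeine in mM (right), on log dose axes with 1 array per dose and no error. The genes in warm colours rose with the caffeine dose, DAL5 by 1.54 per doubling, and those in cold colours fell, DBP2 by -0.97 per doubling.

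The fifth comparison asked the same of 1, 5 and 200 µg/ml rapamycin in W303a. DAL5 (0.66 ± 0.19 per doubling, adjusted p = 0.0473), the aldehyde dehydrogenase gene ALD3 (0.61 ± 0.09), ARG4 (0.60 ± 0.07), ASP3-3 (0.60 ± 0.10) and SRY1 (0.59 ± 0.08) rose most steeply, while GAP1 (0.26 ± 0.12) and MEP2 (0.44 ± 0.16) did not pass. Both passed with only the rapamycin arrays (adjusted p = 0.00659 and 3.86e-07) and without the 5 µg/ml array (0.34 and 0.55, adjusted p = 0.0165 and 0.00528), and MEP2 with a slope on the dose itself through 0 (adjusted p = 0.0443). The rapamycin arrays alone leave 1 residual degree of freedom, so the spread there came largely from other genes. Neither gene rose from 5 to 200 µg/ml (3.35 and 2.81 for GAP1, 5.10 and 4.56 for MEP2). The ribosome assembly genes ENP1 (-0.58 ± 0.06), NOP58 (-0.53 ± 0.07), NOP4 (-0.53 ± 0.07) and NOC3 (-0.53 ± 0.09) and RMT2 (-0.52 ± 0.07) fell most steeply. RPL1B (-0.49 ± 0.07), NOP1 (-0.40 ± 0.09), YHR020W (-0.25 ± 0.06) and the chaperone gene YDJ1 (-0.29 ± 0.07) fell too. The cell wall protein gene PIR3 (0.26 ± 0.07) and the succinyl-CoA ligase gene LSC2 (0.22 ± 0.06) rose.

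In limma's test of the rapamycin slope, 413 of 3688 genes and unnamed probes passed, 119 rising and 294 falling, and 14 lists passed with the preset correlation and 0 with an estimated one. Without the 200 µg/ml array 2 passed, 1 of them MEP2 (2.05, adjusted p = 0.0419), and none of the 413 passed with the 2 doses left. Without the 1 µg/ml array 53 passed. The slope of DAL5 was 2.32 without the 200 µg/ml array (adjusted p = 0.132) and 0.10 without the 1 µg/ml array (0.847), and robust eBayes also ended its call (0.66, 0.0962). Without the 1 µg/ml array ALD3 (0.43, 0.098), ASP3-3 (0.43, 0.149), SRY1 (0.51, 0.0604), NOC3 (-0.64, 0.0601), YDJ1 (-0.39, 0.0698), PIR3 (0.38, 0.0604) and LSC2 (0.33, 0.0604) did not pass either. The lists of ribosomal proteins (81 of 120 fell, or 113 adjusted over the list alone, median slope -0.30), ribosome biogenesis (73 of 112 fell, or 91 with 1 rising adjusted over the list alone, median -0.28), translation factors (11 of 39 fell, or 27 adjusted over the list alone, median -0.18) and tRNA synthetases (4 of 21 fell, or 9 adjusted over the list alone, median -0.11) fell. Vacuolar hydrolases (5 of 13 rose, or 10 adjusted over the list alone, median 0.16) rose. Each had an adjusted p of 0.359 with an estimated correlation. The list of stress-induced genes passed upward in the camera test, but only 3 of its 53 genes rose, also 3 adjusted over the list alone, and the median slope was 0.04. Its adjusted p was 0.514 with an estimated correlation and 0.319 with fry. A further 8 lists passed with all 3 arrays, with an adjusted p between 0.359 and 0.594 with an estimated correlation. Without the 1 µg/ml array, RNA polymerases I and III (median -0.06 against -0.12, adjusted p = 0.0647), nitrogen catabolite repression (0.09 against 0.19, 0.268), DNA damage (0.03 against 0.07, 0.188) and respiration (turned to -0.03, 0.729) did not pass. Without the 200 µg/ml array, autophagy (0.11 against 0.11, adjusted p = 0.0939), cell wall integrity (0.13 against 0.08, 0.171), DNA damage (0.07 against 0.07, 0.32), heat shock (-0.04 against -0.12, 0.709) and amino acid biosynthesis (turned to -0.09, 0.377) did not pass. DNA damage also did not pass with only genes that had every value (0.04, 0.0889). Scaling every array to one spread left 0 genes, and a slope on the dose itself through 0 called 947.

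The last comparison asked which genes differed between strains in the same way under both drugs. Limma's F test over the strain terms passed 0 of 4945 genes and unnamed probes, while 771 had an unadjusted p under 0.05 against 247.2 expected by chance. The smallest adjusted p, 0.142, was shared by ARG1, MET6, FRE4 and DSE1, which were chosen after their values were seen. MET6, methionine synthase, stood at 0.19 in W303a, 1.58 in S288c and 3.54 in Sigma 2000 under rapamycin, and at 0.28, 1.77 and 3.62 under caffeine. ARG1, argininosuccinate synthase, stood at 4.27, 4.25 and 1.38 under rapamycin and at 2.54, 2.44 and -0.56 under caffeine. The additive fit had 2 residual degrees of freedom. In leave-outs chosen after the data were seen, genes passed only where a Sigma 2000 array was dropped. That strain then rested on its remaining array, with fewer residual degrees of freedom. A response to that drug alone or an error of that array would there count as a strain difference.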

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

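The list tests of strain differences and the test of a wrong label for the 1 µg/ml rapamycin array were chosen after the results were seen, and the spread set beside the W303a correlation below was added after its value was known.

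The strain lists below were singled out because strains differed from W303a in the additive fit of drug and strain, with the median difference of log2 ratios and the camera adjusted p at the preset correlation. With an estimated correlation the adjusted p was 0.95 for every one of the 14 lists, and fry called 0. In S288c the median difference was 0.78 for sulfur and methionine genes (adjusted p = 0.0235), 0.41 for stress-induced genes (0.00359), 0.36 for heat shock genes (0.009), 0.31 for genes of the tricarboxylic acid cycle and respiratory chain (0.00769) and 0.54 for mitochondrial ribosomal protein genes (2.23e-09), each 0.95 with an estimated correlation. In Sigma 2000 it was 0.94 for mitochondrial ribosomal protein genes (5.26e-14), 0.55 for sulfur and methionine genes (0.0447), 0.49 for heat shock genes (0.00627), 0.52 for the proteasome (0.0195) and 0.29 for ribosomal proteins (0.0235), and it was -0.44 for amino acid biosynthesis (0.00132), -1.1 for vacuolar hydrolases (0.0447), -0.35 for cell wall integrity (0.0236) and -0.25 for ergosterol genes (0.0297), each again 0.95 with an estimated correlation. Some of these differences were seen mainly under 1 drug. Medians of tricarboxylic acid cycle and respiratory chain genes in S288c and W303a were 0.73 and 0.31 under rapamycin but 0.73 and 0.71 under caffeine. Those of ribosomal proteins in Sigma 2000 and W303a were -2.12 and -2.20 under rapamycin but -1.22 and -1.80 under caffeine. For heat shock genes in Sigma 2000 and W303a they were 0.22 and -0.61 under rapamycin but -0.29 and -0.46 under caffeine. For sulfur and methionine genes in S288c and W303a they were -0.14 and -0.20 under rapamycin but 0 and -0.47 under caffeine. Mitochondrial ribosomal protein genes were higher than in W303a under both drugs in both strains. No group had 4 or more samples, and no array was tested as lying far from its group.

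The first pattern weighed is that the arrays of one strain deviated together under both drugs, with correlations of at least 0.209 between their deviations and above 0.1 in 3 of 3 strains. A strain response and an untreated sample shared by both arrays of a strain predict the same values, so these cannot be told apart without knowing which untreated cells were used. An untreated W303a sample shared by all W303a arrays would have carried the W303a deviation into the low dose arrays, where its highest correlation was 0.0825. The bootstrap interval of that value, 0.0411 to 0.122, spans the bound of 0.1 set before that test was run, so a small shared part may remain. A strain response therefore stays open, as a hypothesis.

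The second pattern is that ribosomal protein genes were lower under rapamycin than under caffeine, by a median of -0.90. A larger response to rapamycin at every gene would not leave this gap, since after scaling caffeine by the slope of the other genes (1.06) the median was still -0.80, with quartiles of -1.05 and -0.57. The gap was not confined to genes with paralogous copies, whose probes may be shared. The 15 ribosomal protein genes without a copy had a median of -0.77. Shared probes mix genes of the same list, so this value says little about whether they widened the gap elsewhere. The gap was seen in 3 of 3 strains (-0.36 in W303a, -1.5 in S288c and -0.82 in Sigma 2000), so 1 strain did not carry it. A difference in how far the chosen doses act stays open as a biological explanation that was not tested, and the authors' normalization could not be examined here.

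The 6 arrays at the highest doses allow 10 splits into 3 and 3, too few for a share under 0.05. For single genes the real split called 0 and the highest other split 0, so 10 of the 10 splits called as many. For gene lists 3 of the 10 splits called as many as the real one, which called 11, and the highest other split called 13. The replicate numbers mark strains, and 4 splits part all 3 strains, of which the real one gave 11 lists and the others 11, 5 and 9. The median difference of ribosomal protein genes was -0.90 in the real split and -0.38, 0.09 and 0.65 in the other splits that part the strains, and -0.67 was the lowest of the splits that part 1 strain. The sign is arbitrary in the other splits, since either group can come first. Each other split that parts the strains is the real one with the arrays of 1 strain exchanged. These splits thus hold part of the drug difference and are no null values. The test of each drug against untreated cells allows 4 sign patterns of 3 arrays, also too few, and 1 of the 4 gave as many genes for each drug. Rapamycin called 1804 genes and the highest other pattern 0, and caffeine called 1958 and the highest other pattern 0. The arrays of a drug resemble each other, so turning the sign of 1 array shrinks the mean and widens the spread of responding genes. A low count was thus fixed in advance, and these patterns are no null values either.

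The third pattern is that the 1 µg/ml rapamycin array resembled no other array. Over the 500 genes that moved most in S288c and Sigma 2000 at 200 µg/ml, its correlation with their mean was 0.258 (bootstrap 0.172 to 0.334), against 0.825 at 5 µg/ml, which lies between the bounds set before that test was run for noise that outweighs the response and for a visible response. Of the ribosomal protein, ribosome biogenesis and nitrogen lists, 1 of 3 lay outside the middle 95% of random lists in the direction of the high dose. These tests decide neither a dose too low for a response nor noise, and both may hold at once. The log2 ratios of the array had an SD of 0.418, against 0.189 and 0.261 on the 0.3 and 1 mM caffeine arrays. A low dose alone does not account for that wider spread, though each value rests on 1 array. The correlation of the 1 µg/ml rapamycin array with the 0.3 and 1 mM caffeine arrays was at most 0.087, while these correlated at 0.557 with each other. The pattern itself is that the array resembles no other array, so a low value here was fixed in advance. This test therefore cannot decide whether a low caffeine array carries the wrong label. Without this array 53 genes passed the rapamycin slope test in place of 413.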

How the results depend on the processing

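Leave-outs of the strain test, and every alternative of the strain list tests, were chosen after the data were seen. Counts of genes stayed within 1.5 times under no further centring, only genes with every value, the median of a gene's probes and robust eBayes in all comparisons. A bound of 2-fold left 1167 genes for rapamycin and 1243 for caffeine, by construction. The array left out set the count, which ran from 821 to 1910 for rapamycin, 1131 to 1752 for caffeine, 0 to 0 for the drug difference, 150 to 937 for the caffeine slope, 2 to 421 for the rapamycin slope and 0 to 72 for strains, with fewer arrays in each fit. Scaling arrays to one spread removes growth of the whole response with dose and enlarges the noise of the low dose arrays. It left 173 genes for the caffeine slope (26 rising and 147 falling, against 310 and 525 of 835) and 0 for the rapamycin slope. Without further centring 224 rose and 543 fell with caffeine. A slope on the dose itself through 0 called 1897 and 947, and the cause was not tested. The strain block changed no call of the drug difference (0 genes) and gave 14 lists in place of 11.

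An estimated correlation left 0 lists for rapamycin, caffeine, the drug difference, both slopes and the strains. Some estimates lay far above the preset 0.01, under rapamycin 0.443 for ribosomal proteins, 0.4 for the proteasome and 0.799 for the mitochondrial ribosome. For such lists the p-values at the preset are likely too small. That test also used fewer degrees of freedom and only genes with every value. Calls ended too where the estimate lay below the preset (under rapamycin 0.00898 for translation factors, 0.000589 for tRNA synthetases and -0.0372 for Yap1 targets). The correlation alone therefore does not account for the loss. Fry called 1 list for the drug difference, G1 and S phase, 6 for the rapamycin slope and 0 for the strains. Of the lists called with the preset correlation, fry also called 12 of 16 for rapamycin, 17 of 17 for caffeine and 15 of 19 for the caffeine slope, but it does not compare a list with other genes. Leaving out 1 array gave 12 to 17 lists for the caffeine slope and 8 to 16 for the strains, and counts within 1.5 times for the others.

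Values that turned were those of the caffeine slope of GAP1 (-0.16 after scaling) and, on leaving out 1 array, those of uncalled genes, of the rapamycin slope, and of the mitochondrial ribosome list under rapamycin (median -0.03 without the Sigma 2000 array against 0.26). Over the leave-outs the rapamycin slope ran from -0.66 to 0.02 for RPL1B, -0.38 to 0.14 for YHR020W, -0.39 to 0.04 for YDJ1, -0.11 to 0.38 for PIR3, -0.13 to 0.33 for LSC2, -0.61 to 0.23 for NOP1, -0.10 to 1.35 for GAP1 and -0.10 to 2.05 for MEP2. Over the leave-outs the rapamycin slope of amino acid biosynthesis genes ran from -0.09 to 0.16 and that of genes of the tricarboxylic acid cycle and respiratory chain from -0.03 to 0.26. HSP12 ran from -0.20 to 0.49 under rapamycin and -0.16 to 2.12 under caffeine, and TOR1 from -0.05 to 0.17 under caffeine. Of 292 gene values under all alternatives, 3094 results stayed on their side of the threshold, 284 no longer passed, 12 newly passed and 12 turned. Signal over background is unknown here and limits what low ratios can show.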

Other observations

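Gene groups differed in how much of their highest-dose change was seen at a middle dose of W303a, where 1 array per dose gives no test. At 5 µg/ml rapamycin the median of nitrogen catabolite repression genes was 2.07, or 93.9% of the 2.21 at 200 µg/ml, over 39 genes measured at both doses. Ribosome biogenesis genes stood at -0.99 against -2.20 (44.8%, 121 genes), and ribosomal protein genes at -0.30 against -2.23 (13.4%, 122 genes). At 3 mM caffeine the same lists stood at 1.49 against 2.82 at 9 mM (53%), -0.89 against -2.17 (40.9%) and -0.16 against -1.82 (8.52%). Cell wall integrity genes stood at 1.03 at 3 mM and 1.01 at 9 mM caffeine (101%), and at 0.12 and 0.41 at 5 and 200 µg/ml rapamycin (29.1%).

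Single genes had different values in different strains, and 0 genes passed the strain test. DUR3, the urea transporter, stood at 1.48 in W303a, 5.11 in S288c and -0.42 in Sigma 2000 under rapamycin, and at 1.23, 3.34 and -0.36 under caffeine. FRE4, a reductase of the iron regulon, stood at -0.93, 0.27 and -4.35 under rapamycin and at -0.77, -0.03 and -3.64 under caffeine. DSE1, a daughter cell gene, stood at 0.91, 0 and 4.08 under rapamycin and at 0.06, -0.65 and 2.60 under caffeine. These genes were chosen after their values were seen, and in that test, with 2 residual degrees of freedom, their adjusted p was 0.165 for DUR3 and 0.142 for FRE4 and DSE1.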
